A study of Homo sapiens with 10 samples.

How the data were processed

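The libraries were prepared from 30 ng of total RNA with the Ion AmpliSeq Transcriptome Human Gene Expression kit, per the labels' protocols. This kit amplifies 1 product per gene, so a value reflects a single stretch of each transcript and carries no correction for length; isoforms that lack the stretch are not counted. The authors deposited RPM, the reads of a gene relative to the library's total, for 20812 genes in 2 tables, 1 for the 5 hepatic lineage libraries and 1 for the 5 organoid libraries; the tables come from separate runs and were normalized separately. The build was hg19, per the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here. The reference annotation at hand belongs to another build, so no coordinates are given; genes are named by the symbols in the tables. A filler of 0.001 RPM in the hepatic lineage table and 0.0001 RPM in the organoid table stood where a gene had no reads, and was set to 0. All values above the filler were whole multiples of one step per library within a tolerance of 0.1 of a step, which gave the reads behind each value and the total reads per library. Reads were used only for depth, for floors of 3 reads and for ratio intervals, since a filler in place of zeros kept the values from being treated as a count table. A total of 2 gene names damaged by a spreadsheet occur 2 times each; these were kept apart by amplicon and are not named. Scaling to total reads makes all genes depend on the most abundant ones, and the most abundant gene held 0.864% of reads at day 8 and 8.66% at day 21.

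Samples were grouped by their labels: 5 days of the hepatic course with 1 library each, 2 LO libraries and 3 BVLO libraries. BVLO was compared with LO by limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with a mean-variance trend, 3 residual degrees of freedom, a two-sided moderated test and Benjamini-Hochberg adjustment over genes with a mean of at least 1 RPM; a gene was called at an adjusted p below 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes. The replicate pairs of a group were compared by chi-square on reads over genes with at least 20 reads. The ratio per degree of freedom was 24.8 for LO and 61.6 to 123 for BVLO, so no pair differed by read counting alone. This does not exclude repeated libraries from the same RNA. A total of 32 gene lists were fixed before the data were examined, and the 31 with at least 5 measured members were tested in limma's camera with a preset correlation of 0.01, beside an estimated correlation and fry. None of the 8 lists called held with the estimated correlation. Within the hepatic course no test was made: the log2 ratio of day 21 to day 8 is given, with the number of genes past 4-fold, and the percentile of a list's median among 10000 random lists of the same size matched on mean expression in 20 bins. Intervals are exact binomial 95% intervals on the reads of 2 libraries; these intervals and the floors cover counting error only, since amplified reads are not independent molecules.

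Genes were named by a rule fixed before the data were examined. For BVLO against LO these were the 10 largest changes in each direction among called genes with a mean of at least 10 RPM and no overlap between groups; for the course, the 10 largest in each direction at 20 RPM or more at day 8 or 21; for each list, its first 1 to 4 members by p or by ratio; and a fixed set of 25 index genes. Some genes that this rule takes in are not reported here. Any other gene named is said to be chosen after its values were seen. The alternatives were other pseudocounts, low-value filters, median-of-ratios and quantile scaling, the replicate number as a block, library weights, a fit without the trend, other list tests, the mean of days 8 and 10 as the start of the course and leaving out each organoid library.

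The code was tested on simulated libraries made from the organoid means and read totals with 200 changed genes, over 13880 genes. Of the genes changed 2-fold that stayed in the test, 32.7% were recovered, and of those changed 4-fold 97.9%, with 3 false calls; a list lowered 4-fold was called and 0 other lists were. Small changes were therefore often missed in this simulation. It drew genes independently, with an SD of 0.307 per library for all genes in both groups. In the data the SD of log2 differences between 2 libraries was 0.317 for the LO pair and 0.572 to 0.753 for the BVLO pairs. A difference between 2 libraries spreads more than 1 library, so these SDs are not to be set directly against 0.307. The spread in the data was unequal between the groups, unlike in the simulation. The estimated correlation reached 0.743, in the cell cycle list, and far more than 200 genes were called. The recovered shares, false calls and list result therefore describe the simulated setting and cannot be carried over to these data. Figures were drawn with matplotlib.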

Results

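The series measured messenger RNA in cells and organoids grown from human induced pluripotent stem cells, which are adult cells returned to a state from which other cell types can be derived. A total of 10 libraries were analysed. They were made with an amplicon panel (Ion AmpliSeq Transcriptome) that reads 1 short product per gene for 20812 genes. A first set of 5 libraries followed the hepatic lineage with 1 library per day: hepatic endoderm (HE) at days 8 and 10, cells labelled IH at days 12 and 14, and cells labelled MH at day 21. The second set held 2 libraries of an organoid labelled LO and 3 of an organoid labelled BVLO. The series title describes a liver organoid that incorporates stem cell-derived blood vessel and contains a tubular bile duct; the labels do not spell out LO, BVLO, IH or MH. The hepatic lineage libraries held 13435987 to 14748445 reads, the LO libraries 15907535 and 17319519, and the BVLO libraries 13806652, 30102128 and 9979979. A level of 3 reads corresponded to 0.0997 RPM in the deepest library and to 0.301 RPM in the shallowest. The labels do not say that the organoid replicates came from separate cultures, so that p-values measure only the spread between these libraries, which may be technical.

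The hepatic lineage libraries addressed how expression changes while endoderm differentiates towards hepatocytes. Secreted liver proteins dominated the difference between day 21 and day 8. AFP, the main serum protein of foetal life, was at 1.12 RPM at day 8, 6163 RPM at day 12 and 36037.5 RPM at day 21. ALB, which encodes serum albumin, came later, at 16.8 RPM at day 12, 229 RPM at day 14 and 28530.5 RPM at day 21. The thyroid hormone carrier TTR was already at 399 RPM at day 8 and 10212 RPM at day 10, and reached 86558 RPM at day 21, a 217-fold ratio with a 95% exact binomial interval of 211 to 223 from the reads. The 10 genes with the largest increase at 20 RPM or more were AFP, the apolipoprotein APOA4, ALB, AHSG, the fibrinogen chains FGB and FGG, the iron carrier TF, the imprinted RNA H19, AGT and SERPINA7, with log2 differences from 14.06 for AFP to 11.56 for SERPINA7. Among the 10 with the largest decrease were the pluripotency-associated RNA-binding protein LIN28A, which went from 1187 to 0.621 RPM, the surface protein CD34, from 802 to 0.138 RPM, the hyaluronan synthase HAS2, from 457 to 0.0690 RPM, and the endoderm markers CXCR4 and CER1, from 416 to 0.759 RPM and from 260 to 0.414 RPM. SOX11, TOP2A, CRABP2, GLIPR2 and HMGA2 completed these 10, at log2 differences of -7.97, -7.70, -7.61, -7.56 and -7.48. With 1 library per day these differences have no replicate check, and the intervals cover counting error only.

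**Figure D1:**
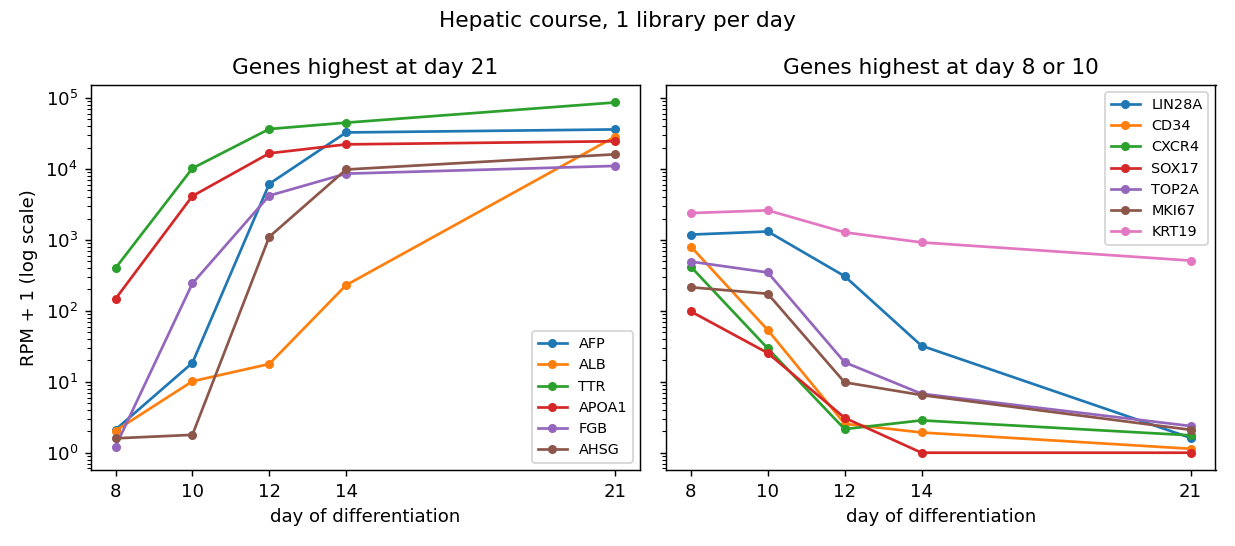
Level of 13 genes at each day of the hepatic course, as RPM plus 1 on a log axis against the day of differentiation; each point is 1 library. ALB stayed at 16.8 RPM at day 12, when AFP was at 6163 RPM, and MKI67 went from 214 RPM at day 8 to 1.10 RPM at day 21.

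The gene groups fixed in advance moved apart over the course. Of 26 plasma protein genes 24 reached a mean of 1 RPM and all of these were at least 4-fold higher at day 21 than at day 8, while A1BG and ITIH3, named after their values were seen, were below that mean and had log2 differences of 0.71 and 1.88. The median log2 difference of the 24 genes, 7.89, exceeded all of 10000 random lists matched on expression. Together the 26 genes of that list went from 1022 RPM at day 8 to 240287 RPM at day 21. Of 19 coagulation and complement genes 18 were at least 4-fold higher (median 5.11), among them CFB, which went from 0.223 to 970 RPM, and CFI. CFI had no reads at day 8, and its level at day 21 was 4084 times a floor of 3 reads. The drug metabolism list had 10 of 12 genes higher (median 4.10), with the sulfotransferase SULT2A1 at 153 RPM and the glucuronosyltransferase UGT2B4 at 118 RPM at day 21. Of 19 urea cycle, amino acid and glucose genes 15 were higher (median 4.30), including HGD and TDO2, both without reads at day 8. The bile acid list had 12 of 16 genes higher and 1 lower (median 4.43). Its members AKR1D1, which reduces bile acid precursors, BAAT, which conjugates bile acids, and the uptake transporter SLC10A1 were at 269, 113 and 57.4 RPM at day 21. CYP7A1, the rate-limiting enzyme of bile acid synthesis, and the bile salt export pump ABCB11 had no reads at day 8 and were at 22.8 and 38.8 RPM at day 21. CYP3A7, the foetal liver cytochrome, was at 56.9 RPM at day 21, although this amplicon may share reads with near-identical family members.

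Proliferation and endoderm genes went the other way. All 25 cell cycle genes were at least 4-fold lower at day 21 (median -5.28), with TOP2A, CDK1 and CENPF at 1.38, 1.10 and 0.552 RPM. The proliferation marker MKI67 was at 173 RPM at day 10 and at 8.81 RPM at day 12. All 13 definitive endoderm and foregut genes were at least 4-fold lower (median -5.12), among them EOMES and SOX17, the latter at 97.0 RPM at day 8 and without reads at days 14 and 21. Of 12 pluripotency genes 7 were lower (median -2.997) and none was higher by that margin. Hepatocyte transcription factors were mixed, with 8 of 19 higher and 4 lower (median 1.14); CREB3L3 and CEBPA were higher, and HNF4A, a master regulator of hepatocyte genes, was at 124 RPM at day 8, 386 RPM at day 10 and 127 RPM at day 21. Of 19 biliary (cholangiocyte) markers 7 were higher and 4 lower (median 1.05). KRT7 had no reads at day 8 and was at 39.9 RPM at day 21, GGT1 and CLDN4 reached 84.4 and 119 RPM, and KRT19 was 4.68-fold lower at day 21 than at day 8 (interval 4.56 to 4.80). Among matched random lists the cell cycle, endoderm and pluripotency medians lay at percentile 0, that of the transcription factors at 99.99 and that of the biliary markers at 100.

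Other groups were smaller or divided. Inflammation and interferon genes were higher for 9 of 14 and lower for 1 (median 2.62), with CXCL2 at 261 and MX1 at 77.7 RPM at day 21, and fibroblast and matrix genes higher for 6 of 18 and lower for 2 (median 1.02), with LOX at 210, COL1A1 at 355 and COL12A1 at 33.0 RPM. The foetal liver list had 7 of 19 genes higher and 4 lower (median 1.37), with SPINK1 and IGF2 without reads at day 8 and at 2570 and 190 RPM at day 21. In the epithelial junction list 4 of 16 were higher and 1 lower (median 0.26), and CDH1 went from 13.5 to 622 RPM and CLDN1 from 39.5 to 1218 RPM. The Notch list had 1 of 13 higher and 4 lower (median -1.48), with NOTCH3 from 131 to 4.69 RPM and NOTCH2 from 179 to 33.6 RPM. The WNT list had 2 of 15 higher and 6 lower (median -1.86, percentile 2.42), with the antagonists FRZB and SFRP1 at 2.21 and 19.1 RPM at day 21. The basement membrane list had 3 of 17 higher and 7 lower (median -1.16), with LAMB3 higher and COL4A6 lower. Since the median of all genes was -0.91, these medians are to be read with their percentile among matched random lists. It was 100 for the inflammation, fibroblast and foetal liver lists, 99.82 for the junction list, 12.52 for Notch and 16.68 for basement membrane. Medians were -0.50 for the TGF-beta list of 21 genes (percentile 85.55), -1.03 for the 14 YAP targets (38.38), -0.84 for 6 venous and lymphatic genes (55.38), -1.26 for 7 septum transversum and stellate genes (25.68) and -1.64 for 5 neural genes (13.69). They were 0.55 for 10 smooth muscle genes (99.35), with TAGLN at 315 RPM, 0.05 for 19 hypoxia and glycolysis genes (98.93), with NDRG1 at 335 RPM, -0.02 for 14 immediate early genes (98.07), 0.15 for 18 unfolded protein and amino acid stress genes (99.78) and 0.38 for 19 cholesterol and lipid genes (99.89). The pan-endothelial list had 0 of 5 genes higher and 2 lower (median 0.65, percentile 93.59), with CD34 lower. It went from 820 to 18.2 RPM in all, of which CD34 alone made up 802 RPM at day 8 and 0.138 RPM at day 21. The arterial list had 2 of 7 higher and 3 lower (median 1.16, percentile 99.52), with CXCR4 and SOX17 lower. It went from 565 to 106 RPM, of which CXCR4 and SOX17 made up 416 and 97.0 RPM at day 8. The fall of both sums thus rests on these 3 genes. The sinusoidal endothelial, intestinal and haematopoietic lists had 2, 3 and 1 measured genes, too few for a percentile.

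Of the 12864 genes with a mean of at least 1 RPM, 931 were at least 4-fold higher and 2477 at least 4-fold lower at day 21 than at day 8 on the log2(RPM + 1) scale. The median gene was at a log2 difference of -0.91, and the 20 most abundant genes held 8.44% of reads at day 8 and 33.5% at day 21. Median-of-ratios scaling turned the split to 1570 higher and 1072 lower genes, so the direction of the majority depends on the scaling. With a pseudocount of 5 RPM there were 586 higher and 1293 lower genes.

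BVLO and LO addressed how the 2 labelled kinds of organoid differ. The largest decrease by log2 difference in BVLO was that of TKTL1, a transketolase-like gene at 153 ± 14.8 RPM in LO (SD, n = 2) and without reads in the 3 BVLO libraries. Its LO mean was 2756 times a floor of 3 reads over the BVLO group. Also lower were SERPINA7, the thyroxine-binding globulin, with a log2 difference of -6.01 (SE 0.35), and SLC10A1, the bile acid uptake transporter, with -5.38 (SE 0.30). FAM19A4, GNG11, EGFLAM, AVPR1A, LGR6, FAM151A and DLGAP3 made up the rest of the 10 genes with the largest decreases, between -6.33 for FAM19A4 and -5.13 for DLGAP3. The 10 with the largest increases were PLA2G2A, a secreted phospholipase, at 8.19 ± 0.237 RPM in LO and 1801 ± 1619 RPM in BVLO (SD, n = 3), CEACAM5, CLCA1, OLFM4, CA9, MUC13, MUC2, CEACAM6, SST and OSR1. CA9, a hypoxia-induced carbonic anhydrase, had a log2 difference of 6.25 (SE 0.30) and values of 0.306 ± 0.189 and 101 ± 33.2 RPM. OLFM4 had no reads in LO and was at 166, 4.58 and 541 RPM in BVLO replicates 1, 2 and 3. Its BVLO mean of 237 ± 275 RPM was 2628 times a floor of 3 reads over the LO group, a ratio that replicate 2 falls far short of. CEACAM5 and CEACAM6 belong to a family of near-identical genes whose amplicons may share reads. All of these 20 genes passed at an adjusted p of 0.0465 or less (limma-trend with Benjamini-Hochberg adjustment). Of them MUC13 lost its call with median-of-ratios scaling (0.0507) and quantile normalization (0.0620).

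In all, 13878 genes were tested, of which 3628 were higher and 1138 lower in BVLO at an adjusted p below 0.05. An unadjusted p below 0.05 was reached by 6666 genes. In 9250 of the tested genes (66.7%) the LO and BVLO values did not overlap, against 20% if the 5 libraries were independent and exchangeable. That is no firm reference, since the SD of log2 differences was 0.317 for the LO pair and 0.572 to 0.753 for the BVLO pairs. The RPM values also carry a shift of the median gene. The median tested gene was 0.43 higher in BVLO on the log2 scale, and the split depended on it: median-of-ratios scaling gave 1735 higher and 2252 lower genes, quantile normalization 1694 and 1890. Of the genes called with median-of-ratios scaling, 1735 higher and 1137 lower genes were also called with RPM, and 0 turned direction. Without LO replicate 1 the counts were 188 and 138 and without LO replicate 2 they were 154 and 111, with the remaining LO library assumed to vary like the BVLO libraries. Of the 109 genes named here for this comparison, a majority lost their call in each of those fits. Among them were CEACAM5, CLCA1, OLFM4, MUC13, MUC2, CEACAM6, SST and OSR1. The liver genes HNF4A, APOA1, AFP, HPD, ASS1 and CEBPA also lost theirs in both fits. So did the Notch genes JAG1, MFNG and LFNG and the endothelial genes PECAM1 and ENG. NOTCH2 lost its call without LO replicate 1. CA9, PLA2G2A and the 10 genes with the largest decreases kept theirs.

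Many plasma protein genes were lower in BVLO. Of 26 plasma protein genes 16 fell and 1 rose, or 17 and 1 adjusted over the list alone, and 16 and 1 with median-of-ratios scaling (median -1.81; camera adjusted p = 1.09e-09, adjusted p = 0.617 with an estimated correlation, and 0.0725 by fry). TTR fell from 65995 ± 15114 RPM to 2282 ± 626 RPM, with a log2 difference of -4.87 (SE 0.37, adjusted p = 0.00061). The retinol carrier RBP4 and the fetuin FETUB fell by 4.21 and 5.01 on the log2 scale, and APOA1 and FGG fell by 2.28 and 2.86. ALB did not follow: its levels were 17361 ± 2654 RPM in LO and 25223 ± 12360 RPM in BVLO (log2 difference 0.40, SE 0.56, adjusted p = 0.587; -0.07 with median-of-ratios scaling). AFP fell by 2.30 on the log2 scale (adjusted p = 0.0321), a call lost with median-of-ratios scaling (0.0594) and quantile normalization (0.0721). Urea cycle, amino acid and glucose genes fell for 9 of 21 and rose for 0, also adjusted over the list alone (median -0.97; adjusted p = 1.43e-05, and 0.602 with an estimated correlation), with HGD, HPD and the urea cycle enzyme ASS1 among them. The cholesterol and lipid synthesis list had 6 of 19 lower and 1 higher, also adjusted over the list alone (median -0.42; adjusted p = 1.43e-05, and 0.602 with an estimated correlation), with the fatty acid synthase FASN lower by 1.35. In the bile acid list 7 of 22 fell and 3 rose, also adjusted over the list alone (median -0.12; adjusted p = 0.00489, and 0.602 with an estimated correlation). AKR1D1 fell by 4.203, and the bile acid receptor NR1H4 rose by 1.28. ABCB11 had a log2 difference of -0.74. Its call was lost without BVLO replicate 1 (limma adjusted p = 0.0730) or 3 (0.0521), and also without either LO library. With median-of-ratios scaling 2 genes of this list were higher and 9 lower, and 0 and 9 of the cholesterol list.

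Other liver groups were not called. Liver transcription factors had 4 higher and 7 lower of 19, or 5 and 7 adjusted over the list alone (adjusted p = 0.0547), with HNF4A at 202 ± 20.3 RPM in LO and 103 ± 26.0 RPM in BVLO (log2 difference -0.998, adjusted p = 0.0221), CEBPA and RXRA lower and ONECUT2 higher. Coagulation and complement genes had 5 higher and 6 lower of 23, or 7 and 6 adjusted over the list alone (adjusted p = 0.359), with KNG1 lower by 1.90. Drug metabolism genes had 8 higher and 5 lower of 22, or 10 and 5 adjusted over the list alone (adjusted p = 0.607); UGT1A1, which conjugates bilirubin and shares exons with its neighbours, rose by 3.79, and FMO5 fell by 1.89. In both of these lists the median and mean were positive and the camera test pointed down. The foetal liver list had 6 higher and 3 lower of 19, also adjusted over the list alone (adjusted p = 0.930), with HMGA2 higher and PEG10 and GPC3 lower. Median-of-ratios scaling gave 2 higher and 8 lower transcription factors, 5 and 6 drug metabolism genes and 2 and 2 foetal liver genes. CYP3A7 was at 246 ± 76.7 RPM in LO and 151 ± 63.2 RPM in BVLO, a difference that did not pass (adjusted p = 0.138, and 0.0460 without BVLO replicate 1).

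The bile duct keratin KRT7 and genes of the Notch pathway, which directs biliary fate, were higher in BVLO. Of 28 cholangiocyte markers 14 rose and 1 fell, or 15 and 1 adjusted over the list alone, against 7 and 2 with median-of-ratios scaling. The list itself did not pass (median 1.16; adjusted p = 0.0524, and 0.602 with an estimated correlation), but passed under both other scalings (0.00593 and 0.00522) and without LO replicate 1 (0.0486), LO replicate 2 (0.0272), BVLO replicate 2 (0.0054) or BVLO replicate 3 (0.0299). KRT7 rose from 0.868 ± 0.161 RPM to 40.5 ± 18.8 RPM, with a log2 difference of 4.35 (SE 0.43, adjusted p = 0.00144). SOX4 rose by 1.40. KRT19 and SOX9 rose by 1.03 and 1.25 with RPM, but lost the call with median-of-ratios scaling (adjusted p = 0.141 and 0.0641). PROM1 fell by 2.28. EPCAM and the chloride channel CFTR did not pass; CFTR was at 11.9 ± 2.80 RPM in LO and 13.3 ± 10.98 RPM in BVLO, and EPCAM passed without BVLO replicate 2 (adjusted p = 0.0300). Of 18 Notch pathway genes 10 rose and 0 fell, or 12 adjusted over the list alone and 6 with median-of-ratios scaling (median 1.24; adjusted p = 0.00609, and 0.602 with an estimated correlation). The receptors NOTCH1 and NOTCH2 rose by 2.30 and 1.53, the ligand JAG1 by 1.85 (adjusted p = 0.0146, and 0.0596 with median-of-ratios scaling), and the glycosyltransferases MFNG and LFNG by 3.78 and 2.36. The target gene HES1 was at 5.58 ± 0.549 RPM and 7.97 ± 1.14 RPM, which did not pass (adjusted p = 0.217).

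Pan-endothelial transcripts were scarce in both kinds of organoid. The arterial list summed to 131 RPM in LO and 336 RPM in BVLO, and the venous and lymphatic list to 259 and 733 RPM. In the day 21 hepatic library, normalized separately, the same lists summed to 106 and 136 RPM. These sums alone therefore do not show endothelial cells. VWF had no reads in any of the 5 organoid libraries, CDH5 was at 1.53 ± 0.0354 RPM in LO and 0.616 ± 0.686 RPM in BVLO, and only 13 of 25 pan-endothelial markers reached a mean of 1 RPM. Of these 4 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.970), and the list summed to 36.9 RPM in LO and 100 RPM in BVLO. PECAM1 rose from 0.697 to 5.67 RPM, EGFL7 by 1.94 on the log2 scale and ENG by 1.76, while KDR was at 3.95 ± 0.366 RPM and 2.61 ± 3.38 RPM, and was called lower without BVLO replicate 3 (adjusted p = 0.00992). The arterial list had 4 of 11 higher, or 7 adjusted over the list alone (adjusted p = 0.170, 0.617 with an estimated correlation, and 0.0469 with median-of-ratios scaling, where the list passed), with CXCR4 and NRP1 up by 2.31 and 2.18. The venous and lymphatic list had 3 of 6 higher, or 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.601), with RELN and NR2F2 up by 2.77 and 1.72, and none of the 3 measured sinusoidal markers passed. With median-of-ratios scaling 2 venous and lymphatic genes were higher and 1 lower, and 0 and 1 sinusoidal markers. The labels mention RNA from planar-cultured and from sorted cells without saying which libraries were sorted. Smooth muscle and pericyte genes had 4 higher and 2 lower of 12, or 5 and 2 adjusted over the list alone (adjusted p = 0.930), with RGS5 up by 3.74 and KCNJ8 and CNN1 lower by 2.49 and 2.95. Median-of-ratios scaling gave 2 and 2. ACTA2 was at 11.2 ± 2.14 RPM and 14.2 ± 0.281 RPM and did not pass.

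Matrix genes were divided. The secreted glycoprotein SPARC fell from 2067 ± 126 RPM to 85.5 ± 10.1 RPM, with a log2 difference of -4.59 (SE 0.18, adjusted p = 9.64e-05). Of the 22 fibroblast and interstitial matrix genes 3 rose and 3 fell, or 1 and 2 adjusted over the list alone (adjusted p = 0.211), with FBN1 lower and BGN higher. BGN lost its call with quantile normalization (adjusted p = 0.0717) and with a pseudocount of 5 RPM (0.0520). COL1A1, at 105 ± 9.95 RPM and 82.7 ± 28.0 RPM, did not pass (adjusted p = 0.312) but was called lower with median-of-ratios scaling (0.0403). Basement membrane genes had 8 higher and 3 lower of 19, also adjusted over the list alone (adjusted p = 0.970), with HSPG2 and AGRN up by 2.13 and 1.63. The septum transversum and stellate list had 1 higher and 1 lower of 9, or 1 and 0 adjusted over the list alone (adjusted p = 0.930). Epithelial junction genes had 3 higher and 4 lower of 17, or 3 and 6 adjusted over the list alone (median -0.51, mean 0.01; adjusted p = 0.0123, 0.777 with an estimated correlation, and 0.270 without BVLO replicate 2). This list lost its call with median-of-ratios scaling (0.0719) and quantile normalization (0.129). Median-of-ratios scaling gave 1 higher and 5 lower fibroblast and matrix genes, 7 and 6 basement membrane genes and 2 and 6 junction genes. CLDN1 fell by 1.95, and GRHL2 and ELF3 rose by 2.71 and 2.50.

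**Figure D2:**
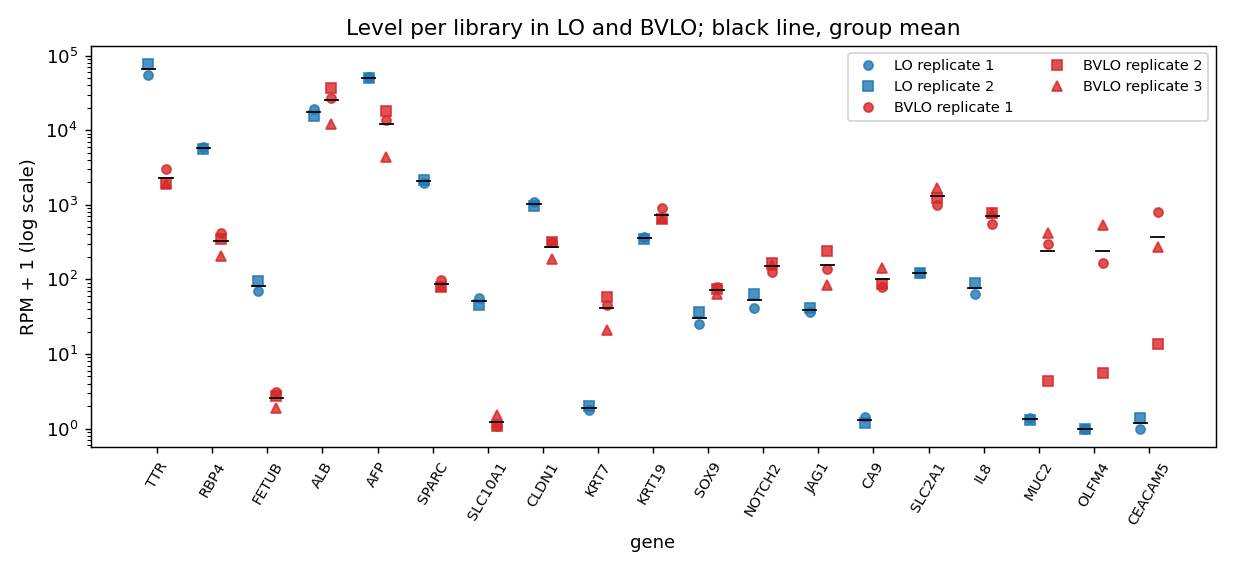
Level of 19 genes in the 2 LO and 3 BVLO libraries, as RPM plus 1 on a log axis; each symbol is 1 library and each black line a group mean. TTR lies at 65995 RPM on average in LO and 2282 RPM in BVLO, while ALB overlaps, and MUC2, OLFM4 and CEACAM5 are far lower in BVLO replicate 2 than in replicates 1 and 3.

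Hypoxia and inflammation genes were higher in BVLO. Of 20 hypoxia and glycolysis genes 14 rose and 2 fell, also adjusted over the list alone, against 11 and 2 with median-of-ratios scaling (median 1.33; adjusted p = 0.00713, and 0.617 with an estimated correlation). The glucose transporter SLC2A1 rose from 121 ± 0.895 RPM to 1296 ± 336 RPM, EGLN3 by 3.88 and PFKFB3 by 2.62 on the log2 scale. Of 19 inflammation and interferon genes 12 rose and 0 fell, or 15 adjusted over the list alone and 10 with median-of-ratios scaling (median 1.83; adjusted p = 0.000964, and 0.602 with an estimated correlation). The neutrophil chemokine IL8 rose from 75.6 ± 18.1 RPM to 706 ± 129 RPM, and CXCL1, ICAM1 and the acute phase protein CRP rose by 2.80, 1.95 and 2.76. Immediate early genes had 9 higher and 0 lower of 19, or 10 adjusted over the list alone (adjusted p = 0.0547), with JUNB and IER3 up by 2.19 and 2.64; this list passed with median-of-ratios scaling (0.0222), quantile normalization (0.00553), and without LO replicate 1 (0.0184) or BVLO replicate 2 (0.00491), all with the preset correlation. With an estimated correlation its adjusted p = 0.777 over all libraries. The unfolded protein and amino acid stress list had 5 higher and 5 lower of 20, also adjusted over the list alone (adjusted p = 0.0617), with PSPH lower and VLDLR higher; median-of-ratios scaling gave 1 higher and 7 lower, and the list was called lower without BVLO replicate 1 (0.00681) and with a 10 RPM filter (0.0448), both with the preset correlation. With an estimated correlation its adjusted p = 0.777 over all libraries. TGF-beta genes had 9 higher and 3 lower of 23, or 10 and 3 adjusted over the list alone (adjusted p = 0.601), with TGFB1 and ID1 up by 2.53 and 1.95 and ID2 lower by 1.04. WNT genes had 7 higher and 3 lower of 17, or 8 and 4 adjusted over the list alone (adjusted p = 0.601), with NKD1 and LGR5 up by 4.17 and 3.51 and SFRP1 lower by 3.07, and YAP targets had 4 higher and 3 lower of 16, also adjusted over the list alone (adjusted p = 0.601), with WWTR1 and TEAD4 up and F3 lower. Median-of-ratios scaling gave 7 higher and 7 lower WNT genes and 3 and 4 YAP targets, and quantile normalization 5 and 3 TGF-beta genes. Of 25 cell cycle genes 3 rose and 1 fell, and 0 adjusted over the list alone (adjusted p = 0.344). With median-of-ratios scaling 0 rose and 3 fell, and without BVLO replicate 2 the list was called lower than other genes with the preset correlation (0.0224). With an estimated correlation its adjusted p = 0.932 over all libraries. MKI67 was at 17.4 ± 0.569 RPM and 26.7 ± 7.197 RPM and did not pass, and CENPE rose with RPM but not with either other scaling (adjusted p = 0.149 and 0.250).

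Intestinal genes were uneven between the BVLO libraries, and the list was not called. Of 14 intestinal and pancreatic genes 7 rose and 1 fell, also adjusted over the list alone (median 2.32; adjusted p = 0.114, and 0.777 with an estimated correlation). The list passed with median-of-ratios scaling (0.00593), quantile normalization (0.00616) and without BVLO replicate 2 (3.19e-05). The mucin MUC2, made by goblet cells, was at 295, 3.29 and 412 RPM in BVLO replicates 1, 2 and 3, and the intestinal stem cell marker OLFM4 at 166, 4.58 and 541 RPM. Leaving out BVLO replicate 1 ended the call for OLFM4, MUC13 and MUC2 (adjusted p = 0.0678, 0.114 and 0.0963), and MUC13 and MUC2 also lost it without BVLO replicate 3 (0.0916 and 0.0755). The 3 genes lost it with a pseudocount of 5 RPM (0.0664, 0.0790 and 0.0751) and with no filter on low values (0.0522, 0.0844 and 0.0722) as well. Lysozyme (LYZ), at 9.62 ± 6.32 RPM in LO and 348 ± 124 RPM in BVLO, and TFF3 and PDX1, which rose by 4.13 and 1.56, held in all BVLO leave-outs, but TFF3 and PDX1 lost their call without LO replicate 1 (0.0784 and 0.0636) or 2 (0.0859 and 0.0664). LYZ is also in the haematopoietic list, which had 3 higher and 0 lower of 6, also adjusted over the list alone (adjusted p = 0.359) with CD68 up by 1.64. The neural list had 2 higher and 0 lower of 10, also adjusted over the list alone (adjusted p = 0.601), with STMN2 and TUBB3 higher, the latter not with median-of-ratios scaling (adjusted p = 0.138). Pluripotency genes had 3 higher and 1 lower of 8, also adjusted over the list alone (adjusted p = 0.601), with L1TD1 and SOX2 up by 1.53 and 2.90, and median-of-ratios scaling gave 3 and 2. Definitive endoderm genes had 3 higher and 1 lower of 8, or 4 and 1 adjusted over the list alone (adjusted p = 0.445).

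**Figure D3:**
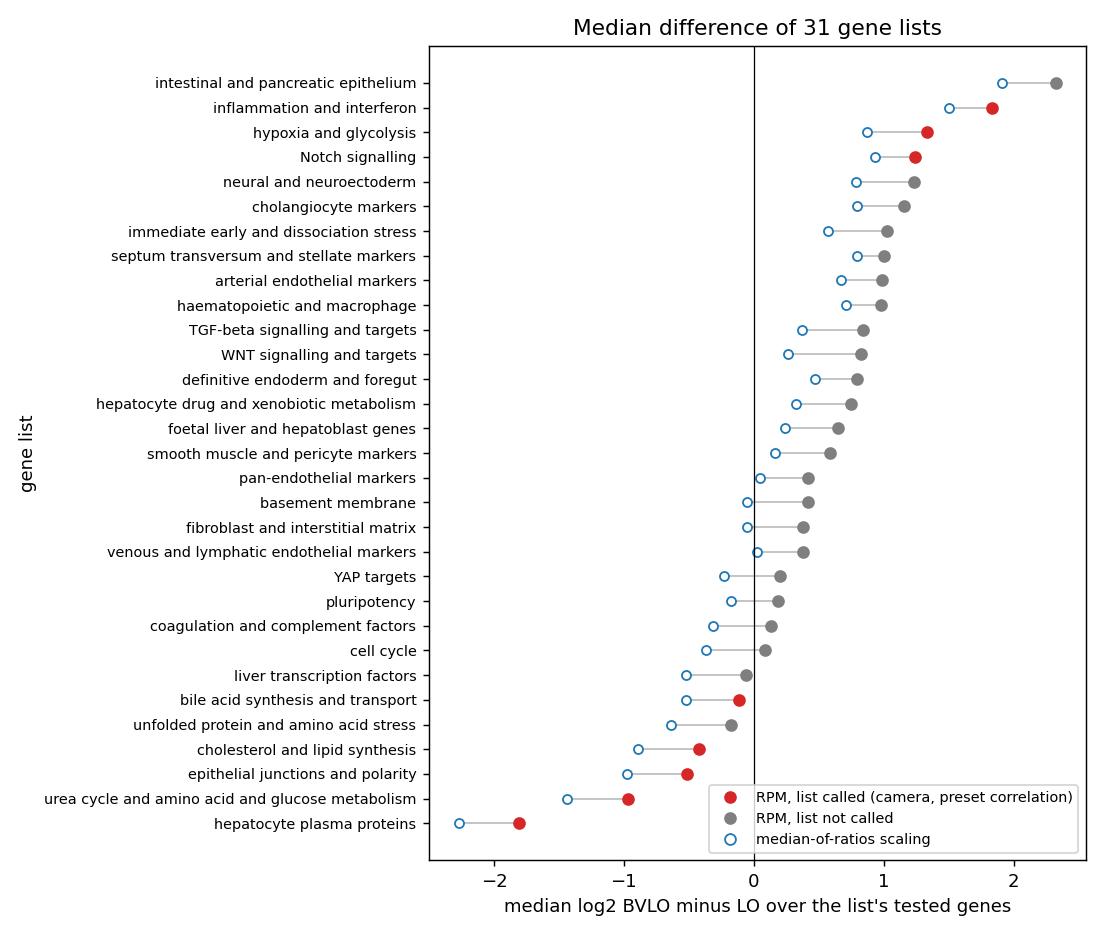
Median log2 difference, BVLO minus LO, over the tested genes of 31 lists, with RPM (filled) and with median-of-ratios scaling (open); red marks lists with an adjusted p below 0.05 by camera with its preset correlation. The plasma protein list lies at -1.81 and -2.27 and the inflammation list at 1.83 and 1.503, while medians such as that of the YAP targets, at 0.20 and -0.23, change sign with the scaling.

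The organoid and hepatic lineage tables were normalized separately, so levels across them are set side by side without a test. TTR was at 86558 RPM at day 21, 65995 RPM in LO and 2282 RPM in BVLO. APOA1 was at 24569, 24283 and 5262 RPM in the same order, and ALB at 28530.5, 17361 and 25223 RPM. KRT7 was at 39.9 RPM at day 21, 0.868 RPM in LO and 40.5 RPM in BVLO. SOX9 was at 4.83, 29.7 and 71.2 RPM, and JAG1 at 7.79, 38.3 and 154 RPM. CYP7A1 was at 22.8 RPM at day 21 and at 1.09 and 0.872 RPM in LO and BVLO, and the adult liver cytochrome CYP3A4 was at or below 0.272 RPM in every group mean and day. COL1A1 was at 355, 105 and 82.7 RPM. The plasma protein list summed to 240287 RPM at day 21, and to 160788 and 183391 RPM in the LO libraries and 52925, 69556 and 25933 RPM in the BVLO libraries.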

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

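Every alternative below was planned before the data were examined. Higher and lower calls in BVLO stayed within 1.5 times of 3628 and 1138 for both other pseudocounts and both low-value filters. This also held without the trend and with library weights. The replicate block gave 3865 and 1351 (3416 and 1100 also called without it). It gives BVLO replicate 3, alone in its block, no weight, so it does not test all 5 libraries. Median-of-ratios scaling gave 1735 and 2252, quantile normalization 1694 and 1890; the share of higher calls fell from 76.1% to 43.5% and 47.3%, by the construction of these scalings, which remove the median shift of 0.43. Leaving out 1 library gave 154 to 4858 higher and 111 to 1264 lower genes, lowest without LO replicate 2 and highest without BVLO replicate 2. As a check for pairing, deviations of same-numbered LO and BVLO libraries correlated at 0.115 and 0.192 across genes. LO replicate 1 and BVLO replicate 3, which share no number, correlated at 0.116. Over only 2 pairs this does not establish pairing. With the block, 5 lists were higher, the cholangiocyte and immediate early lists (both at adjusted p = 0.0137) in addition; ABCB11 and CENPE were not called (0.0503 and 0.0525), KDR was called lower (0.00854), and no other named gene or list changed its call. The lists called higher numbered 3 with RPM, 6 with no filter, 5 with a 10 RPM filter, 7 with median-of-ratios scaling, 6 with quantile normalization, 0 with an estimated correlation and 8 by fry; those called lower numbered 5 with RPM and with no filter, 7 with a 10 RPM filter, 4 with median-of-ratios scaling, 4 with quantile normalization, 0 with an estimated correlation and 0 by fry, which tests a list on its own and not against other genes. Leave-one-out ranges were 3 to 6 higher and 5 to 6 lower lists. Except where the alternative's construction is named, the cause was not tested.

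Among genes named for BVLO against LO, directions turned only where no call was made: ALB (-0.0671) and ACTA2 (-0.11) with median-of-ratios scaling, HES1 (-0.10) and ACTA2 (-0.15) with quantile normalization, and CFTR, which ranged from -1.04 without BVLO replicate 3 to 0.66 without BVLO replicate 2. Calls were also lost by APOA1, AFP and CENPE with no filter (adjusted p = 0.0766, 0.217 and 0.0722), SOX2 with a pseudocount of 5 RPM (0.0550), TUBB3 with quantile normalization (0.0768), MUC13 and MUC2 without the trend (0.0638 and 0.0536) and CENPE without BVLO replicate 3 (0.0546), and EPCAM gained one with library weights (0.0433). With no filter the cholangiocyte, intestinal and immediate early lists passed (0.0242, 0.0304 and 0.0211), with a 10 RPM filter the intestinal and immediate early lists (0.0322 and 0.0423) and, lower, the transcription factors (0.0423), and with a pseudocount of 0.1 RPM the cholangiocyte list (0.0410); with an estimated correlation and RPM, these lists had an adjusted p of 0.602 to 0.777. Lists whose camera test turned direction were not called in either fit. The test rests on moderated statistics, so its turn does not mean that the mean of a list changed sign. The mean log2 difference of these lists from that of all genes was 0.34 for pan-endothelial and 0.25 for smooth muscle genes with a pseudocount of 0.1 RPM. It was 0.19 for haematopoietic genes with no filter, and 0.63 and 0.37 for smooth muscle and basement membrane genes with a 10 RPM filter. With median-of-ratios scaling it was 0.24 for drug metabolism, 0.21 for pan-endothelial, 0.21 for smooth muscle and 0.0231 for basement membrane genes. With quantile normalization it was 0.20, 0.10, 0.11 and 0.0853 for the same lists and 0.0298 for WNT genes, and with the replicate block 0.31 for smooth muscle genes. With 1 library left out, it ranged from -0.21 to 0.12 for foetal liver, 0.0209 to 0.43 for pan-endothelial, -0.0626 to 0.26 for smooth muscle, -0.0379 to 0.0876 for basement membrane, -0.0844 to 0.32 for pluripotency, 0.21 to 0.65 for septum transversum and -0.0726 to 0.25 for venous genes.

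In the hepatic course, the 931 higher and 2477 lower genes became 586 and 1293 with a pseudocount of 5 RPM, and 1570 and 1072 with median-of-ratios scaling; 592 were higher with a 10 RPM filter, which tests 8961 genes, and both counts stayed within 1.5 times with the mean of days 8 and 10 as the start. Of 66 genes followed over the course, 48 moved beyond their counting interval with a pseudocount of 5 RPM, 33 with 0.1 RPM, 36 with median-of-ratios scaling and 26 with the other start; of 29 list medians 5 moved with 0.1 RPM, 5 with median-of-ratios scaling, 1 with no filter and 1 with the other start. The 2 planned count models on reads were not run, since the zeros of the tables had been replaced by a filler. Depth limits the low genes: in the shallowest library 3 reads are 0.301 RPM.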

Other observations

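The tests of this part were chosen after the values they bear on had been seen, except the test on HOX genes, whose bounds were set before. Genes that were lower in BVLO overlapped with genes that were higher late in the hepatic course. After median-of-ratios scaling, and with the course ratio centred on its median, 395 of 12474 genes measured in both tables were called and at least 4-fold lower in BVLO. Of these 234 (59.2%) were at least 4-fold higher at day 21 than at day 8, where 46.8 would be expected of independent lists, and 15 were lower. Of 147 genes at least 4-fold higher in BVLO, 28 were lower and 40 were higher at day 21, where 10.7 and 17.4 would be expected. The comparisons share no libraries, and genes are not independent replicates. Over 13878 genes, the course day with the highest Spearman correlation was day 14 for both LO libraries (0.938 and 0.943) and day 21 for the 3 BVLO libraries (0.824, 0.819 and 0.767), though day 12 was close to day 21 for BVLO replicates 2 (0.814) and 3 (0.760).

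More genes were called higher than lower in BVLO, 76.1% of calls. The share was 43.5% after median-of-ratios scaling, but this scaling centres the median gene (at -0.0089), so that a near-even split follows from it and says nothing on the source of the excess. A candidate source is that a few abundant genes take a larger share of the reads in LO: the 20 genes with the highest LO level held 28.8% of LO and 14.8% of BVLO reads. Picking genes by their LO level favours a larger share in LO. The 20 most abundant genes of each library itself held 28.0% and 29.8% of reads in LO and 15.2% to 20.4% in BVLO. Without the 20 genes highest in LO the median difference was 0.201 instead of 0.428 (0.145 to 0.242 with each library left out), and 2319 genes were higher and 1650 lower. The value alone lay just past the bound set against this source, and the range was required to lie past it only after that had been seen. Removing genes with a larger share in LO lowers the median by construction, and the remainder depends on how many are removed. The test therefore cannot decide how much of the shift abundant genes account for. Whether the rest lies in RNA content or in other genes stays open.

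Of the 14 tested intestinal list members 7 were called higher in BVLO, 1 lower and 6 not. The 11 members with a BVLO mean of at least 10 RPM were higher in BVLO replicates 1 and 3 than in both LO libraries. A filter on the BVLO level favours this outcome. A candidate explanation is that non-hepatic epithelial cells were present in unequal shares. Of these members 7 (63.6%) were at least 4-fold lower in BVLO replicate 2 than in replicate 1, between the bounds set for and against it; LYZ, LGR5, PDX1 and VIL1, listed after their values were seen, were not, at 290, 33.7, 38.0 and 102 RPM in replicate 2. CDX2 and CDH17, also chosen after their values were seen, were at 47.5 and 28.8 RPM and at 37.2 and 26.6 RPM in LO, and at 11.9 and 23.1 RPM in BVLO replicate 2, below both. So were CDX1, chosen in the same way, at 1.20 RPM against 2.83 and 1.39 RPM in LO, and VIL1, against 185 and 142 RPM in LO. CDX2 was at 134 and 120 RPM in BVLO replicates 1 and 3. Posterior gut patterning was tested on HOX genes of the posterior groups: their median difference was 1.33, past the bound set in advance, but only HOXB6 and HOXB9 reached the filter, neither was called (limma adjusted p = 0.235 and 0.208 with the same scaling), and both were highest in BVLO replicate 1. A minimum of 5 genes, as for the lists, was required only after this was seen, and under it the test decides nothing.

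Of 26 plasma protein genes 16 were called lower in BVLO, ALB not among them. Dilution of hepatocyte RNA by cells that lack these transcripts would lower them alike. Whether other cells in BVLO lacked them was not tested. The SD of their log2 differences was 1.82, against a median SE of 0.378 for one gene. FETUB was at -5.01 and ITIH3, chosen after its values were seen, at 1.68. Relative to the LO mean, ALB was at 0.66, 1.08 and -0.53 in BVLO replicates 1, 2 and 3, and TTR at -4.44, -5.05 and -5.12. This spread argues against dilution by such cells as the whole cause, though the bounds were set with these values known. The list's median was -1.55, -1.27 and -2.43 in BVLO replicates 1, 2 and 3, where the intestinal list summed to 2645, 545 and 2889 RPM. An order over 3 libraries cannot decide whether dilution was a part of the cause. Replicates 1 and 3 also differed in the median at similar intestinal sums. Dilution as a part stays open. A first test, that the median of replicate 2 was still low, went against dilution and was set aside because it rests on 1 library. An earlier stage on the hepatic course may contribute: over the 26 genes, the Spearman correlation of the difference with the rise from day 8 to day 21 was -0.259, between the bounds set for and against it. This test replaced a first one on the closest course day, whose values stand above and went against an earlier stage, by a narrow margin in BVLO replicates 2 and 3. Along the course TTR preceded ALB, the opposite of their order in BVLO. The vessel component that the series title names was not tested apart from these, and which libraries came from sorted cells is not stated.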
